A study of Mus musculus with 12 samples.

How the data were processed

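RNA of C2C12 mouse myoblasts was measured on Illumina mouse expression BeadChips in 12 samples, which form 6 groups of 2 arrays. Per the labels, each group received a scrambled siRNA (siSCR), an siRNA against BRM (siBRM) or an siRNA against BRG1 (siBRG1) at 100 nM, and was collected 18 h or 48 h after the change to differentiation medium. BRM is the product of Smarca2 and BRG1 that of Smarca4. Nothing in the sources used here says whether the 2 replicates of a group were separate cultures, so the p-values measure only the spread between these samples.

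The deposited intensities of the first table are bead-averaged fluorescence signals per probe on a linear scale, with no normalization seen in the values. The deposited detection p-values compare each probe with the negative controls of its own array. Per the file headers, that table also holds, as other units, the number of beads per probe and the bead standard error of the signal. The second deposited table holds intensities with nearly the same quantiles on every array (medians from 248.7 to 249.3). They rank the probes of each array as the first table does. The authors' values there are therefore taken as quantile normalized without background subtraction. The submitters' processing notes name GenomeStudio 2009.1, and the further steps are not given in the sources used here.

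The array carries 45281 probes, of which 34885 had 1 gene symbol, 18 had several and 10378 had none. The background of the unnormalized signals was inferred from the detection p-values with the normexp method in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with an offset of 16. The arrays were then quantile normalized and the signals taken to log2. A probe was tested when its detection p was under 0.05 on at least 2 arrays, which left 20415 probes and 10847 genes. A gene was read from its tested probe with the highest mean over the 12 arrays, and 4219 genes had several tested probes. For siBRM and siBRG1 against siSCR, all probes of such a gene had the same sign in 44.6% and 51.9% of them at 18 h. At 48 h it was 46.6% and 54.5%. The directions of genes given below are those of 1 probe each.

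The limma model gave each of the 6 groups its own mean without a block term and left 6 residual degrees of freedom. Its moderated tests were two-sided, with Benjamini-Hochberg adjustment over the tested probes, and an adjusted p under 0.05 counted as a call. The comparisons were each targeting siRNA against siSCR at each time, siBRM against siBRG1 at each time, siSCR at 48 h against 18 h, and the difference of each siRNA effect between the times. Gene lists fixed beforehand were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, on the 25 lists with at least 5 tested genes. Both p-values of camera were adjusted over these lists within a comparison. The samples, comparisons, lists, named-gene rule and first set of alternatives were chosen before the data were examined.

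The array barcodes place the samples on 3 BeadChips. The first holds the 18 h samples of replicate 1, the second the 48 h samples of replicate 1, and the last all 6 samples of replicate 2. In every set the siSCR array precedes the siBRM array, and the siBRG1 array comes last. The deviations of the replicates from their group means correlated between groups with r from 0.449 to 0.825 over 15 pairs of groups, so the replicate numbers pair the samples. Blocked fits therefore took the BeadChip as a fixed term (4 residual degrees of freedom), the replicate as a single fixed term (5) or the BeadChip as a random term. The median residual variance was 0.4407 without a block and 0.1097 with the BeadChip as a fixed term. Standard errors given below after ± come from the fit without a block, so they include the shift between BeadChips. Under the fixed BeadChip term, the step between the times averaged over the siRNAs rests on the last BeadChip alone, because each of the other 2 holds 1 time. Those 2 still enter the comparison of siSCR between the times, through the differences of siSCR from the other siRNAs.

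The named genes are Smarca2 and Smarca4, the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, and for each list up to 4 called members or, where none was called, the 2 with the smallest adjusted p. A fixed set of myogenic, cell-cycle and control genes is open to naming as well. Where a gene was at background on the array of 1 group in a replicate, its difference there is given as a lower bound against the detection limit of that array, the lowest detected signal. A gene at background on both arrays of a group is given as a bound on the mean. In list medians held at the bound, a gene at background on both arrays of a replicate, or with no bound left, counted as unchanged. These medians are thus pulled towards no difference. Genes called by the random BeadChip term are named in addition, and were chosen after their values were seen.

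The test of siBRG1 against siSCR at 48 h, and no other, was tried on simulated data with known changes and the observed spread. The BeadChip shifts were the mean of each BeadChip minus the overall mean. The first 2 BeadChips hold 1 time each, so these shifts also hold part of the difference between the times. Without a block the test recovered 0% of the genes changed 2-fold, 4-fold or 8-fold. In data simulated without BeadChip shifts it recovered 4.48%, 89.6% and 98.5%. With the BeadChip as a fixed term it recovered 1.49%, 86.6% and 100% with 3 false calls, and with the random term 2.99%, 88.1% and 100% with 7 false calls. Camera was tried on these data without a block only. It called a simulated list of 38 genes lowered by 1 on the log2 scale with both correlations, and 0 of 24 unchanged lists. The lists were random genes, with noise drawn separately for each gene. They cannot show how often camera at the preset correlation calls unchanged lists whose genes vary together.

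Alternatives covered the background correction, the scaling, the authors' normalized values, the detection filter, the block, the variance model, the summary of probes and the omission of each array. Omitting an array without a block breaks the pairing of the replicates, so each omission was also run with the BeadChip as a fixed term, chosen after seeing the data. Unless said otherwise, values with an array left out come from the fit without a block. The closing section gives their effects. The number of arrays limits the precision. Bead counts served as a check of the arrays, bead standard errors as a check of 1 probe, and probes without a symbol were kept in the adjustment but are not named.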

Results

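C2C12 cells are an immortalized mouse myoblast line that fuses into myotubes after serum is reduced. They were given siRNA against either ATPase of the SWI/SNF chromatin remodelling complexes, BRM (gene Smarca2) or BRG1 (gene Smarca4), or a scrambled siRNA. Transcripts were measured at 18 h and 48 h of differentiation on 12 arrays, 2 in each of 6 groups. The question set by the series is which genes depend on BRM, on BRG1 or on both. The mean signal of an array was 513 to 545.9 on the first BeadChip, 664.9 to 794 on the second and 1218 to 1644 on the third. Between 27.33% and 39.37% of the probes were detected. Arrays of different groups on 1 BeadChip at 1 time correlated more closely (r from 0.95 to 0.991 across probes) than the 2 replicates of a group (r from 0.847 to 0.922). The first principal component held 55.6% of the variance and parted the replicates, and the second held 18.1% and parted the times.

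Each siRNA target was lower in its own group in both replicates at both times, though no target passed the test in limma (adjusted p = 1 for each). Smarca2 differed from siSCR by -1.17 ± 0.79 on the log2 scale (SE, n = 2) in siBRM cells at 18 h, with -0.71 and -1.63 in replicates 1 and 2. At 48 h it differed by -0.59 ± 0.79, with -0.71 and -0.48. These SE include the shift between BeadChips, which cancels from the difference within a replicate. With the BeadChip as a block, the standard error of 1 replicate's Smarca2 difference at 48 h was 0.44. Smarca4 in siBRG1 cells was above background in replicate 2 alone, where it differed from siSCR by -1.05 at 18 h and -1.43 at 48 h. In replicate 1 it was at background with siBRG1, which bounds it at least 1.07-fold lower at 18 h and at least 3.98-fold lower at 48 h. The fitted differences of -1.21 ± 0.86 and -1.94 ± 0.86 include these background values. In siBRG1 cells at 48 h the Smarca2 signal was 0.77 above siSCR (0.85 and 0.68), while Smarca4 in siBRM cells differed by 0.14 at 18 h and by -0.12 at 48 h. With the BeadChip as a block, Smarca4 at 48 h had limma's adjusted p = 0.171 and passed under other normalizations with this block, for example with median scaling (-1.92, adjusted p = 0.0138). The mean of the 2 tested Smarca2 probes, 1 of them at background on 9 of the 12 arrays, differed by -0.28 at 18 h and -0.29 at 48 h, and without background correction Smarca4 differed by -0.58 at 18 h and -0.99 at 48 h.

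**Figure D1:**
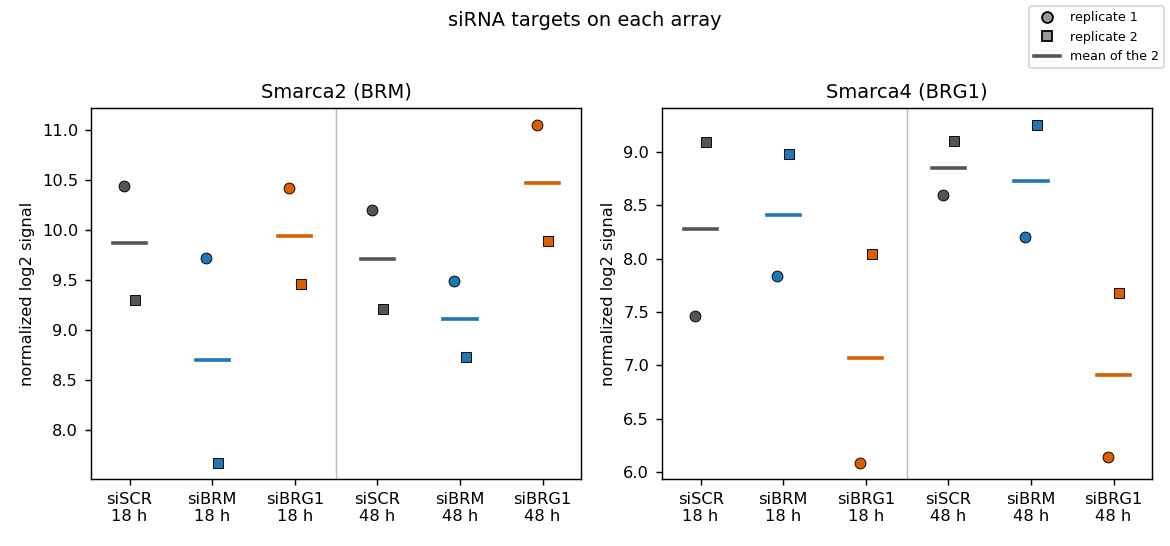
Normalized log2 signal of Smarca2 (left) and Smarca4 (right) on each of the 12 arrays, by siRNA and time; circles are replicate 1, squares replicate 2 and lines the mean of the 2. Smarca4 averages 6.91 in siBRG1 cells (1 of 2 arrays at background) and 8.85 in siSCR cells at 48 h, and Smarca2 averages 8.70 in siBRM cells and 9.87 in siSCR cells at 18 h.

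Differentiation of the siSCR cells from 18 h to 48 h gives the scale for the siRNA effects. Genes of the contractile apparatus rose, with a median log2 difference of 2.91 over the 38 tested sarcomere genes (camera adjusted p = 1.23e-48, and 0.00101 with an estimated correlation). Genes of muscle calcium handling and energy metabolism rose by a median of 2.08 (7.11e-31 and 0.00528), and genes of myoblast fusion, membrane and synapse rose by a median of 1.19 (1.54e-16 and 0.0029). Of the sarcomere genes 34 were higher at 48 h in both replicates. Adjusted over the list alone, 29 sarcomere genes rose and 1 fell, and 11 rose when adjusted over all probes. In the calcium and energy list 18 of 30 genes rose when adjusted over the list alone and 5 over all probes, and in the fusion list 9 of 29 and 1. With the BeadChip as a block and an estimated correlation 0 lists were called between the times (0.0508 for the sarcomere, 0.0982 for calcium and energy and 0.0794 for fusion). With genes at background held at their bound against the detection limit, the 3 medians were 2.86, 2.08 and 1.05.

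Over all genes, limma called 35 between the times, of which 33 rose and 2 fell. Cox6a2, a muscle subunit of cytochrome c oxidase, rose by 5.69 ± 0.74 (SE) on the log2 scale, and the calcium buffer of the sarcoplasmic reticulum Casq2 rose by 5.21 ± 0.55. The fast troponin C gene Tnnc2 by 4.31 ± 0.41, the M-band gene Myom2 by 4.15 ± 0.52, the myosin light chain gene Myl4 by 4.0 ± 0.52 and skeletal actin Acta1 by 3.47 ± 0.43. Hrc rose by 3.91 and the sarcoglycan Sgca by 4.2. The muscle LIM protein Csrp3 and the ryanodine receptor Ryr1 rose as well, by 5.66 and 3.19 in replicate 2, and were at background at 18 h in replicate 1 (at least 9.46-fold and 15.5-fold higher at 48 h). For genes at background at 18 h only a bound can be given, which was at least 19.4-fold higher for the titin-associated Ankrd2, 12.8-fold for Chil1, 12.6-fold for Fn3k, 11.4-fold for Tmem182, 9.38-fold for Ablim3 and 5.68-fold for the glycogen phosphorylase gene Pygm. The keratin gene Krt13 was at least 7.71-fold lower and the integrin gene Itgb7 at least 7.52-fold lower at 48 h.

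The myogenic transcription factor list had a median log2 difference of 1.29 (camera adjusted p = 6.47e-07; adjusted p = 0.0543 with an estimated correlation). Its member Myog, which drives terminal differentiation, differed by 2.67 ± 0.60 and had limma's adjusted p = 0.213 without a block and 0.0106 with the BeadChip as a block. Myod1 differed by 2.14 and Mef2c by 1.92. The muscle creatine kinase gene Ckm differed by 5.42 in replicate 2 and was at background at 18 h in replicate 1 (at least 15.6-fold higher at 48 h). The median of the myogenic factors was 0.86 with genes at background held at their bound. Proliferation genes had lower medians at 48 h. The median was -0.93 for the 46 genes of G1/S and DNA replication (9.58e-12; adjusted p = 0.107 with an estimated correlation) and -0.93 for the 51 genes of G2/M and mitosis (2.08e-13; adjusted p = 0.0957 with an estimated correlation). The replication licensing gene Cdc6 differed by -2.11, the kinetochore gene Nuf2 by -1.29 and cyclin D1 (Ccnd1) by -1.85, none of them called. With the BeadChip as a block, 33 of the G1/S genes and 32 of the G2/M genes fell when adjusted over the list alone, and 2 and 1 rose. Over all probes 1 and 2 fell. The shift was larger in replicate 2 (-1.51 and -1.45) than in replicate 1 (-0.41 and -0.42). Leaving out 1 siSCR array moved these medians without ending a call. That of the myogenic factors was 0.43 without replicate 1 at 18 h, 2.01 without replicate 1 at 48 h and 0.11 without replicate 2 at 48 h. That of G1/S was -1.46 and -0.55 without replicates 1 and 2 at 48 h, and that of G2/M was -0.49 without replicate 2 at 48 h.

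The list of the integrated stress and unfolded protein response had a median of 0.91 (2.55e-05; adjusted p = 0.107 with an estimated correlation), with Herpud1 at 1.89 and Chac1 at 2.46. Without replicate 2 of siSCR at 48 h that median was 0.11 with adjusted p = 0.131, and without replicate 1 it was 1.68. Cholesterol biosynthesis genes had a median of -0.56 (0.00208; adjusted p = 0.0543 with an estimated correlation), with the lanosterol synthase gene Lss at -1.56, and adjusted p = 0.155 without replicate 2 of siSCR at 18 h. The Notch pathway had a median of 0.56 (0.0222; adjusted p = 0.19 with an estimated correlation) and the cell-cycle inhibitors one of 0.16 (0.0251; adjusted p = 0.107 with an estimated correlation). Both of the last lists lost their call with the BeadChip as a block (0.15 and 0.0617). The Notch list also lost it under median scaling (0.0892) and without replicate 1 at 18 h (0.122), replicate 1 at 48 h (0.39) or replicate 2 at 18 h (0.0704), and the inhibitor list without replicate 1 at 18 h (0.279) or replicate 2 at 48 h (0.115). The median of the inhibitor list was 0.44 without replicate 1 at 48 h and 0.70 without replicate 2 at 18 h. The housekeeping genes Gapdh and Actb differed by -0.01 and -0.30, and the housekeeping list did not pass (median -0.13).

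The replicate 1 arrays of the times sit on different BeadChips, so within replicate 1 the time and the BeadChip cannot be told apart. Replicate 2, all on 1 BeadChip, gave medians of 3.20 for the sarcomere, 2.64 for calcium and energy genes and 1.06 for fusion genes. The count of 35 was 179 (151 higher, 28 lower) with the BeadChip as a block, 287 (198 and 89) with the replicate as a block, 300 (223 and 77) with the BeadChip as a random term, and 0 under median scaling. It was 16 without replicate 1 of siSCR at 48 h, and 0 without replicate 1 at 18 h, replicate 2 at 18 h or replicate 2 at 48 h. Omissions combined with the BeadChip block gave 0 to 940. Of the 7 list calls between the times that ended without a block when 1 array was left out, 2 held with it.

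**Figure D2:**
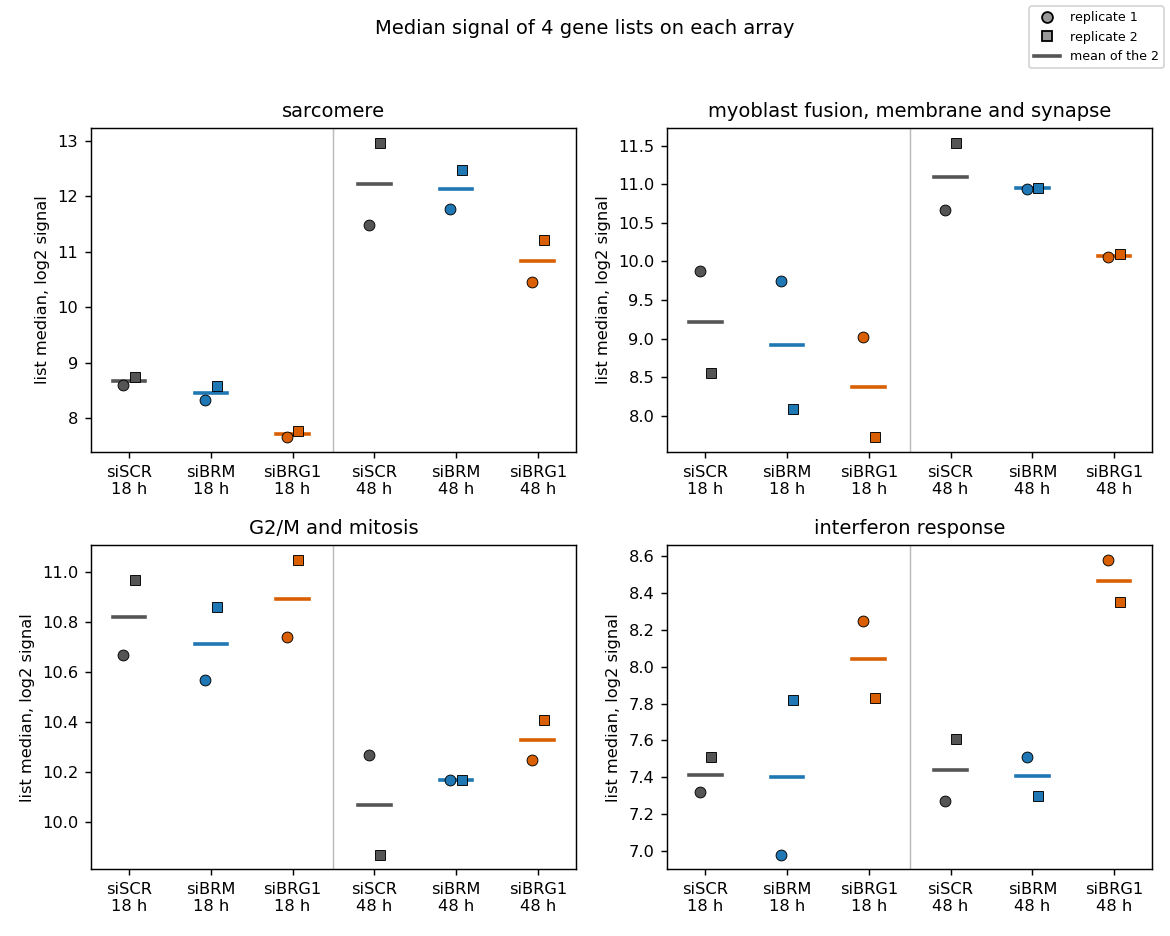
Median log2 signal of the tested genes of 4 lists on each array, by siRNA and time; circles are replicate 1, squares replicate 2 and lines the mean of the 2. The sarcomere medians at 48 h are 11.49 and 12.97 with siSCR, 11.78 and 12.47 with siBRM, and 10.46 and 11.22 with siBRG1.

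With siBRG1 at 18 h, the sarcomere list was lower than with siSCR. It had a median log2 difference of -0.81 (-0.60 and -0.82 in replicates 1 and 2), with camera's adjusted p = 3.49e-15, and with an estimated correlation 0.0263 without a block and 0.303 with the BeadChip as a block. Of its 38 genes 28 were lower in both replicates. Other lists passed with the preset correlation alone (with an estimated correlation, adjusted p = 0.0561 for fusion and 0.222 to 0.34 for the rest). Fusion and membrane genes had a median of -0.44, calcium and energy genes one of -0.50, extracellular matrix genes one of -0.28 and Notch pathway genes one of -0.57. Interferon response genes had a median of 0.44, with 0.46 and 0.41 in the replicates. Many of these genes are near background at 18 h, and 19 of the 38 sarcomere genes were detected on all 4 arrays.

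With genes at background held at their bound, the sarcomere median was -0.44 (-0.17 and -0.75 in the replicates), that of fusion -0.31, calcium and energy -0.34, matrix -0.29, Notch -0.35, interferon 0.27 (0 and 0.28) and the myogenic factors -0.05. These bounds were chosen after seeing the data, and genes counted as unchanged pull the medians towards 0. In replicate 2, where both arrays were above background, the M-band gene Myom3 differed by -1.27, the skeletal myosin light chain kinase gene Mylk2 by -1.09 and the membrane repair gene Dysf by -0.81. In replicate 1 they were at background with siBRG1, and at least 1.46-fold, 3.18-fold and 1.64-fold lower. The muscle cadherin Cdh15 differed by -0.87. Basement membrane nidogen (Nid1) differed by -1.42 and Thbs1 by -1.16. Among the myogenic factors Myod1 differed by -1.13 (-1.34 and -0.92), Myog by -0.78 (-0.33 and -1.22) and Tead4 by -0.74. In the Notch list Hey1 differed by -0.70 but Hes1 by 0.66. The immunoproteasome gene Psmb8 differed by 0.79 in replicate 2 and was at least 3.02-fold higher in replicate 1, and the interferon regulatory factor Irf1 differed by 0.82. The osteoblast and chondrocyte markers had a median of 0.79 over 7 genes (1.06 and 0.34), but 2 of the 7 were detected on all 4 arrays. With genes at background held at their bound or counted as unchanged the median was 0, which so few detected genes can give by rule.

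No single gene was called by limma at this time (0 genes, with 128 at an unadjusted p under 0.05, where 542 of the 10847 tested genes are expected by chance). Blocked fits also called 0, with 657, 570 and 749 genes at that level for the fixed BeadChip term, the fixed replicate term and the random BeadChip term. The 542 assumes a spread free of BeadChip shifts, which the fit without a block does not have. A count below 542 in that fit is no evidence against an effect, here or below. With the BeadChip as a block, 13 sarcomere genes were lower when adjusted over the list alone and 0 over all probes, and 8 lists were called as without the block. Apart from the sarcomere, the list calls rest on the preset correlation. The adjusted p moved from 1.87e-05 to adjusted p = 0.0561 with an estimated correlation for fusion, from 9.38e-05 to 0.222 for matrix, from 0.000229 to 0.227 for calcium and energy, from 0.00358 to 0.222 for interferon, from 0.00855 to 0.227 for Notch, from 0.00855 to 0.222 for the osteoblast markers and from 0.0302 to 0.34 for the myogenic factors (median -0.19). With the BeadChip block, camera with an estimated correlation called none of them, the sarcomere included.

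Leaving out 1 array without a block leaves its group on 1 BeadChip, so the shift between the replicates enters the difference. Of the 14 calls at this comparison that such omissions ended, 4 held with the BeadChip as a block. Without replicate 2 of siSCR, 1 list stayed past the threshold, the sarcomere, and 2 did with the block. Without the block the adjusted p was then 0.0534 for fusion, 0.0534 for matrix, 0.136 for calcium and energy, 0.268 for Notch, 0.0819 for interferon and 0.218 for the osteoblast markers, and the median of the myogenic factors was 0.06 (-0.17 with the block). The call ended for Notch (0.286), the osteoblast markers (0.508) and the myogenic factors (0.286) without replicate 1 of siBRG1. It ended for calcium and energy (0.136), interferon (0.686) and the myogenic factors (0.163) without replicate 2 of siBRG1. The omission of replicate 1 of siSCR ended it for interferon (0.106, against 1.53e-06 with the block), and there the median of the myogenic factors was -0.30. The fusion median was -0.19 without replicate 1 of siBRG1, and 5 lists passed without either siBRG1 array. The myogenic factors also lost it under median scaling (0.0936) and with the authors' normalized values (0.0587).

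With siBRG1 at 48 h, the 3 muscle lists that rose during differentiation were lower than with siSCR. The sarcomere median was -1.07 (-0.89 and -1.43 in replicates 1 and 2), with 35 of 38 genes lower in both replicates. Calcium and energy genes had a median of -1.0 (-0.79 and -1.63), with 25 of 30 lower in both, and fusion and membrane genes one of -0.78 (-0.63 and -1.09), with 22 of 29. Without replicate 1 of siSCR the sarcomere median was -1.69 and that of calcium and energy -1.73, and without replicate 2 of siSCR the sarcomere median was -0.70. With genes at background held at their bound, the sarcomere, calcium and energy, fusion and interferon medians were -1.06, -0.98, -0.76 and 0.50. Interferon response genes rose, with a median of 0.51 (0.57 and 0.51) and 20 of 27 genes higher in both replicates. The adjusted p was 5.52e-26 for the sarcomere, 2.91e-19 for calcium and energy, 5.57e-15 for fusion and 1.02e-08 for interferon, and 0.00385, 0.0186, 0.00385 and 0.019 with an estimated correlation. With the BeadChip as a block and an estimated correlation none of them passed (0.0874, 0.169, 0.0874 and 0.0874).

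Among sarcomere genes, the thin-filament nucleator Lmod3 differed by -2.5 ± 0.73 (SE; -2.66 and -2.34 in the replicates) and Myom3 by -1.84 ± 0.50 (-1.56 and -2.11). The glycogen phosphorylase gene Pygm differed by -1.94, the fast calcium pump Atp2a1 by -1.39 ± 0.44, Dysf by -1.36 ± 0.41 and Sgca by -1.52. Ckm differed by -1.85 (-1.32 and -2.37) and Tnnt3 by -1.33. The myogenic factor list had a median of -0.70 (0.000711; adjusted p = 0.178 with an estimated correlation), with Tead4 at -1.19, Ankrd2 at -1.74, Mef2c at -0.99, Myod1 at -0.97 (-0.30 and -1.64) and Myog at -0.70 (-0.66 and -0.75). Genes that restrain myogenesis did not pass as a list (median 0.26), and of 17 genes 10 were higher and 3 lower in both replicates. Twist2 differed by 1.11 and Snai2 by 0.87, against -0.53 for the differentiation inhibitor Id1. In the interferon list Psmb8 differed by 1.91 in replicate 2 and Oasl2 by 1.69 in replicate 1. In the other replicate each was at background with siSCR (at least 4.92-fold and 4.74-fold higher with siBRG1), and these 2 genes passed when adjusted over the list alone, with 0 over all probes.

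Proliferation genes had higher medians than with siSCR at 48 h. The median was 0.42 for G2/M and mitosis (3.58e-05; adjusted p = 0.307 with an estimated correlation) and 0.41 for G1/S and DNA replication (0.00265; adjusted p = 0.399 with an estimated correlation). In replicate 1 these medians were 0.10 and -0.07, and in replicate 2 they were 0.76 and 0.69. The condensin gene Smc2 differed by 1.28, Nusap1 by 0.94 and cyclin D2 (Ccnd2) by 1.14. Immediate early genes had a median of 0.51 (0.00512; adjusted p = 0.214 with an estimated correlation), with Egr2 at 1.92, and the Notch pathway had one of -0.59 (0.00323; adjusted p = 0.178 with an estimated correlation), with the ligand gene Dll1 at -1.77 and the target Nrarp at -1.1 in replicate 2 (at least 3.7-fold lower in replicate 1). The stress response list had a median of 0.28 (0.0462; adjusted p = 0.385 with an estimated correlation, and 0.136 with the BeadChip as a block), with Trib3 at 4.55 in replicate 1 and 0.44 in replicate 2. Without replicate 2 of siSCR the medians were -0.01 for G2/M, -0.09 for G1/S and -0.01 for the immediate early genes, and that of the myogenic factors was -0.07 (adjusted p = 0.607). The call also ended for G1/S (0.0945) and the myogenic factors (0.19) without replicate 1 of siBRG1, for Notch (0.289) and stress (0.205, median -0.26) without replicate 1 of siSCR, and for stress (0.683) without replicate 2 of siBRG1. Calls that held had medians of -1.09 (myogenic factors), 0.84 (G1/S) and 0.76 (G2/M) without replicate 1 of siSCR, 0.24 (G2/M) and -0.30 (Notch) without replicate 2 of siBRG1, 0.47 (stress) without replicate 1 of siBRG1, and 1.05 (stress) without replicate 2 of siSCR. Of the 9 calls ended by these omissions 2 held with the BeadChip as a block, where 10 ended.

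For single genes limma called 0 at 48 h, with 218 at an unadjusted p under 0.05 (542 expected by chance). In data simulated for this comparison the fit without a block missed even 8-fold changes, and the other comparisons were not simulated. The fixed BeadChip and replicate terms also called 0, with 1150 and 999 at that level, and the random BeadChip term called 11. Of these 11, chosen for naming after their values were seen, 8 were higher with siBRG1. They were the cadherin-pathway gene Fjx1 (3.07, adjusted p = 0.0303), the growth factor gene Ccn2 (2.92, 0.0303), Col8a2 (2.27 in replicate 1, at least 4.71-fold higher in replicate 2), Bmper (2.07), Erfe (1.89), Ch25h (1.89), the guanylate-binding protein gene Gbp2b (at least 3.15-fold higher) and Tex19.2 (at least 2.3-fold higher). The 3 lower genes were Lmod3 (adjusted p = 0.0487), the phosphodiesterase gene Pde2a (-2.24) and the nucleoporin gene Nup210, which was at least 2.35-fold lower. With the fixed BeadChip term, 25 sarcomere, 14 calcium and energy, 9 fusion and 5 myogenic factor genes were lower and 9 interferon genes higher when adjusted over the list alone, with 0 over all probes. Other normalizations with that term, chosen after seeing the data, called 80 to 274 genes.

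**Figure D3:**
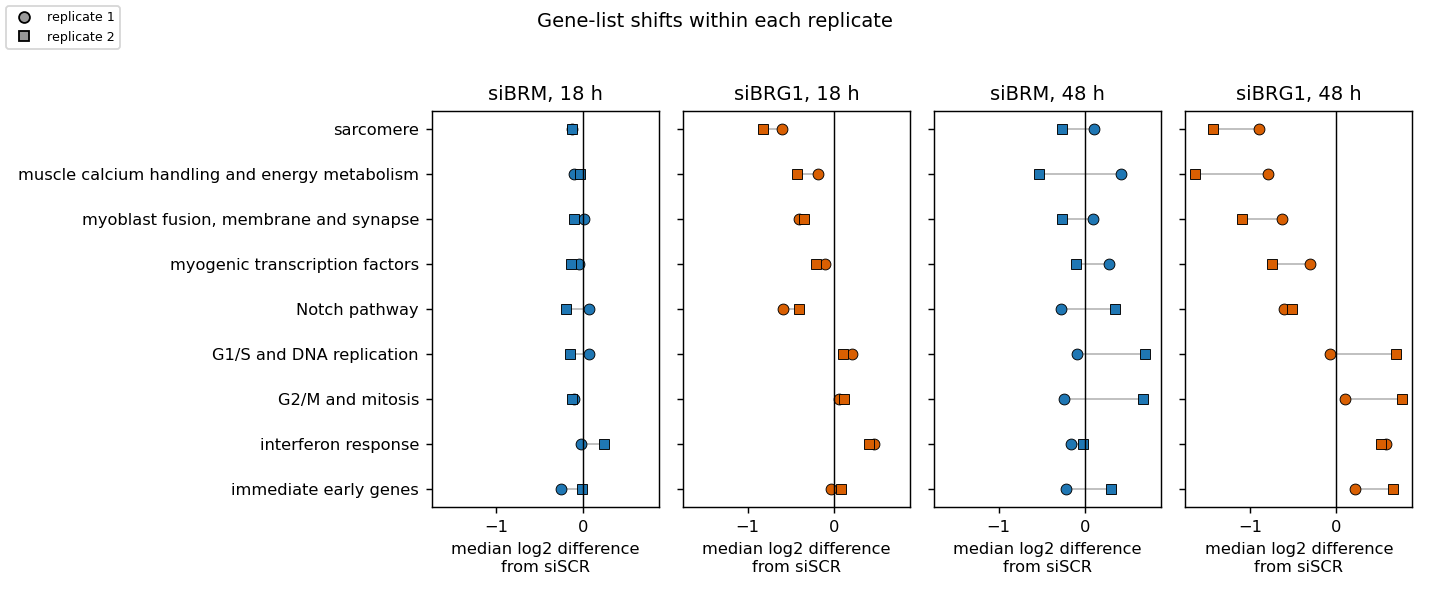
Median log2 difference from siSCR of 9 gene lists within replicate 1 (circles) and replicate 2 (squares) for siBRM and siBRG1 at 18 h and 48 h; grey lines join the replicates. The sarcomere list lies at -0.89 and -1.43 with siBRG1 at 48 h, against 0.10 and -0.27 with siBRM.

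The siBRG1 effect on the muscle lists differed between the times by camera with the preset correlation. The 48 h effect minus the 18 h effect had a median of -0.34 for the sarcomere (0.00428), -0.70 for calcium and energy (4.38e-06) and -0.26 for fusion (0.00317). Each had adjusted p = 0.271 with an estimated correlation. At 18 h, 19 of 38 sarcomere, 12 of 30 calcium and energy and 17 of 29 fusion genes were detected on all 4 arrays. At 48 h it was 33, 23 and 21. Background limits how far siBRG1 could lower the others at 18 h, and no bound was computed for the difference between the times. A larger effect at 48 h therefore cannot be told apart from this limit. Without replicate 2 of siSCR at 48 h these differences were -0.04 (adjusted p = 0.989), -0.26 (0.452) and -0.23 (0.341). The sarcomere call also ended without replicate 1 of siBRG1 at 48 h (0.118), replicate 2 of siSCR at 18 h (0.0896) or replicate 2 of siBRG1 at 18 h (0.119), and the fusion call without the last 2 of these (0.0528 and 0.0661). The sarcomere difference was -0.94 without replicate 1 of siSCR at 48 h, and the fusion difference -0.17 without replicate 1 of siBRG1 at 48 h. The sarcomere difference without replicate 2 of siSCR at 48 h was 0.02 (adjusted p = 0.741) with the BeadChip as a block. No gene was called by limma for this difference (0, with 61 at an unadjusted p under 0.05 against 542 expected by chance, and 477, 404 and 506 with the fixed BeadChip, fixed replicate and random BeadChip terms, each with 0 calls).

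With siBRM at 18 h, 1 list differed from siSCR. The sarcomere median was -0.17 (-0.13 in each replicate; camera adjusted p = 0.0132, and adjusted p = 0.604 with an estimated correlation), with 15 of 38 genes lower in both replicates and 1 higher in both. The median was -0.10 with genes at background held at their bound. Its members Casq2 and Klhl40 differed by -0.15 and -0.06 in replicate 2 and were at background with siBRM in replicate 1 (at least 1.32-fold and 2.3-fold lower). Outside the muscle lists Col1a2 differed by -0.88, Jun by -0.73, and the smooth muscle gene Tagln by 0.70 in replicate 2 (at least 1.29-fold higher in replicate 1). Myod1 and Myog each differed by -0.12.

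The sarcomere call at 18 h ended under median scaling (adjusted p = 0.196) and without any 1 of the 4 arrays compared (0.152 and 0.338 without replicates 1 and 2 of siSCR, 0.416 and 0.196 without those of siBRM). Without replicate 1 of siBRM 2 lists passed, and without each of the other 3 arrays 0 did. Of these 4 lost calls 1 held with the BeadChip as a block. Limma called 0 genes with 34 at an unadjusted p under 0.05, and the fixed BeadChip, fixed replicate and random BeadChip terms called 0 with 280, 224 and 328. All lie below the 542 expected by chance, which does not show the absence of an effect. The effects of the 2 replicates correlated across genes with r = 0.02.

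With siBRM at 48 h, the 2 replicates moved apart. Proliferation lists had medians of -0.10 (G1/S and DNA replication) and -0.24 (G2/M and mitosis) in replicate 1, and 0.69 and 0.67 in replicate 2. Muscle calcium and energy genes had medians of 0.41 and -0.54, and the stress response list of 0.72 and -0.83. The sarcomere list had a median of -0.01 (0.10 and -0.27) and did not pass. Across all genes the 2 replicate effects correlated with r = -0.35, and 37.5% of the genes had the same sign in both. Genes are not independent replicates. The difference of siBRM and siBRG1 at 48 h, which leaves out the siSCR arrays, correlated between the replicates with r = 0.39. That of siBRG1 and siSCR at 48 h, which holds the same siSCR arrays, correlated with r = 0.20.

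Averaged over the replicates, the G1/S list had a median of 0.22 (0.00385; adjusted p = 0.941 with an estimated correlation) and the G2/M list one of 0.20 (0.0345; adjusted p = 0.976 with an estimated correlation). The replication gene Gins2 differed by 0.71 (-0.01 and 1.43) and Smc2 by 1.0 (0.29 and 1.71), while cyclin A2 (Ccna2) and the primase gene Prim1 were above background on 1 of the 4 arrays each. Myc differed by -1.12 in replicate 2 and was at background with siBRM in replicate 1 (at least 1.34-fold lower), and Ccn2 differed by 1.44 (0.84 and 2.03). Values that differed in sign between the replicates include Myod1 (0.67 and -1.30), Ccnd1 (-0.76 and 1.41), Rb1 (-0.45 and 1.09) and Ckm (0.69 and -0.85). Under median scaling, where the median of all genes was -0.26, the 2 proliferation medians were -0.12 and -0.17, and without replicate 2 of siSCR they were -0.18 and -0.20. Their adjusted p was 0.539 and 0.619 without replicate 2 of siBRM. The medians were 0.77 and 0.58 without replicate 1 of siSCR, and without replicate 1 of siBRM that of G1/S was 0.13. The number of lists called was 2, but 6 and 4 without replicates 1 and 2 of siSCR and 0 without replicate 2 of siBRM. Of the 4 calls ended by omissions 0 held with the BeadChip as a block, where the G2/M median without replicate 2 of siSCR was -0.20 (adjusted p = 0.0164). Limma called 0 genes with 17 at an unadjusted p under 0.05, and the fixed BeadChip, fixed replicate and random BeadChip terms called 0 with 243, 181 and 224. All lie below the 542 expected by chance, which does not show the absence of an effect. With a block, the opposed replicates still enter the spread.

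**Figure D4:**
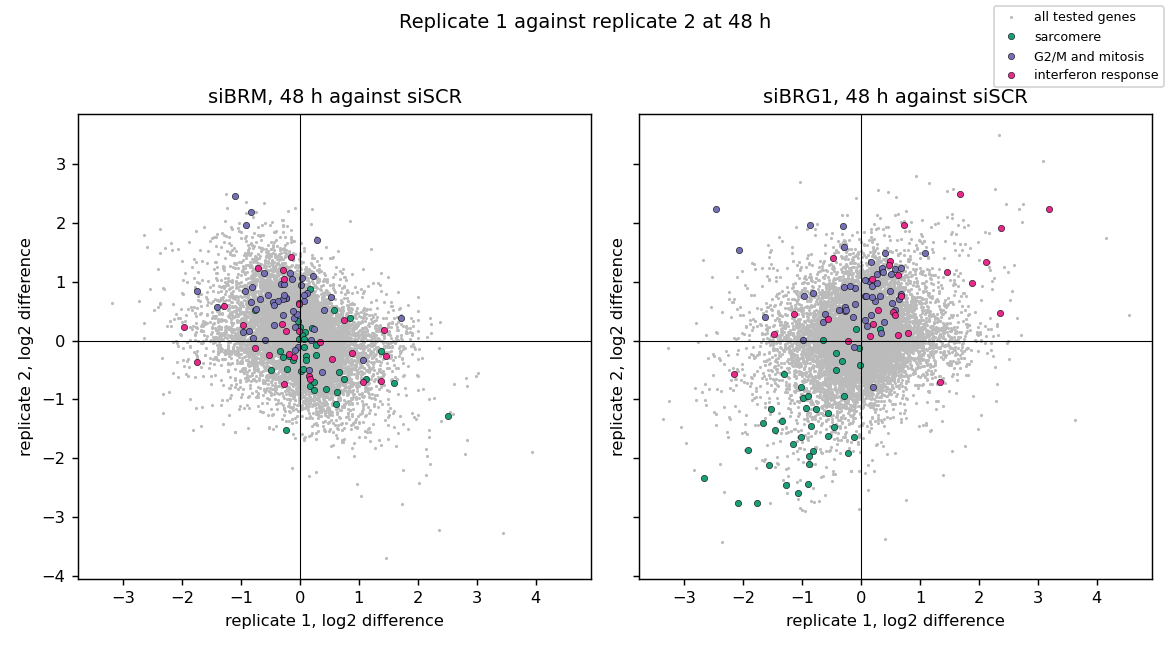
Log2 difference from siSCR at 48 h in replicate 1 (horizontal) and replicate 2 (vertical) for each tested gene (grey) and the members of 3 lists (colours), with siBRM on the left and siBRG1 on the right. The correlation across genes is -0.35 with siBRM and 0.20 with siBRG1, and 35 of 38 sarcomere genes are lower in both replicates with siBRG1.

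Set against each other, the 2 siRNAs differed in the muscle lists at both times by camera with the preset correlation. At 18 h the sarcomere median of siBRM minus siBRG1 was 0.46 (7.71e-07; adjusted p = 0.0942 with an estimated correlation), with 0.47 and 0.51 in the replicates. The fusion median was 0.30 (0.000123; adjusted p = 0.0942 with an estimated correlation), that of calcium and energy 0.39 (0.000438; adjusted p = 0.332 with an estimated correlation) and that of the matrix 0.17 (0.0411; adjusted p = 0.35 with an estimated correlation). The 4 medians were 0.23, 0.25, 0.26 and 0.14 with genes at background held at their bound. In replicate 2 Mylk2 differed by 1.29, Myom3 by 1.19, Dysf by 0.96 and the fusion-linked protease Adam12 by 0.68, and in replicate 1, at background with siBRG1, they were at least 2.89-fold, 1.34-fold, 1.42-fold and 1.13-fold higher with siBRM. The oxidase subunit Cox7a1 differed by 1.40. The fusion call at 18 h ended without replicate 1 of siBRM (0.145) or replicate 2 of siBRG1 (0.0592), that of calcium and energy without replicate 2 of siBRM (0.152) or of siBRG1 (0.159), and that of the matrix without any 1 of the 4 arrays (0.177 to 0.297). Without replicate 1 of siBRG1 the sarcomere median was 0.295 and the fusion median 0.55, and without replicate 2 of siBRM the fusion median was 0.58. The 4 lists called became 2 without replicate 1 of siBRM and 1 without replicate 2 of siBRG1, and 9 with the authors' normalized values. Of the 8 calls ended by omissions 1 held with the BeadChip as a block.

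At 48 h the 3 muscle lists differed between the siRNAs, while the matrix median was 0.01. Whether these differences changed between the times was not tested. The sarcomere median was 1.12 (1.07 and 1.08 in the replicates), with 36 of 38 genes higher with siBRM in both. The calcium and energy median was 0.93, with all 30 genes higher in both replicates, and the fusion median was 0.68. Interferon genes were lower with siBRM, with a median of -0.71 (-0.63 and -0.73). Without a block these 4 lists passed with both correlations (1.08e-26, 1.16e-20, 1.3e-12 and 2.88e-10, and 0.00562, 0.0123, 0.00629 and 0.0123 with an estimated correlation). With an estimated correlation and the BeadChip as a block none of them passed (0.0661, 0.145, 0.105 and 0.0661). Without replicate 2 of siBRG1 the interferon median was -0.39. Myom3 differed by 1.82, the muscle phosphoglycerate mutase gene Pgam2 by 2.46, Dysf by 1.38 and Psmb8 by -1.59. In replicate 2 the titin-cap gene Tcap differed by 1.73, the caveolin gene Cav3 by 1.38, the Notch target Nrarp by 2.04 and Oasl2 by -1.27. In replicate 1 the first 3 were at background with siBRG1 (at least 5.32-fold, 3.67-fold and 4.11-fold higher with siBRM) and Oasl2 with siBRM (at least 3.72-fold lower). With genes at background held at their bound, the sarcomere, calcium and energy, fusion and interferon medians were 1.03, 0.89, 0.63 and -0.41.

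Further lists passed at 48 h with the preset correlation alone. They were the myogenic factors (0.65, and 0.36 with genes at background held at their bound; 1.09e-05, and adjusted p = 0.0838 with an estimated correlation), Notch (0.49, 0.0015; 0.132), immediate early genes (-0.41, 0.00903; 0.236), G2/M and mitosis (-0.20, 0.0252; 0.539), the stress response (-0.32, 0.0257; 0.427) and inflammatory cytokines (-0.32, 0.0325; 0.292). The call ended for the myogenic factors without replicate 1 of siBRG1 (0.0616), for Notch without replicate 2 of siBRM (0.156), and for immediate early genes without replicate 1 of siBRM (0.0805), replicate 1 of siBRG1 (0.0518) or replicate 2 of siBRG1 (0.075). It ended for G2/M without replicate 1 of siBRM (0.359) or replicate 2 of siBRG1 (0.34), and for inflammatory cytokines without the same arrays (0.372 and 0.476) and under median scaling (0.0764). The stress list lost it with the BeadChip as a block (0.0524), without replicate 2 of siBRG1 (0.593) and without replicate 2 of siBRM (0.411), where its median was 0.03. Without replicate 1 of siBRG1 the medians were -0.57 for stress and 0.74 for Notch, and without replicate 2 of siBRG1 that of the myogenic factors was 1.03. Of the 11 calls ended by omissions 2 held with the BeadChip as a block, where 11 ended.

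No gene was called by limma between the siRNAs at either time (0 genes each, with 147 at 18 h and 205 at 48 h at an unadjusted p under 0.05, and 542 expected by chance). The fixed BeadChip term called 0 with 736 and 878, the fixed replicate term 0 with 626 and 777, and the random BeadChip term 0 at 18 h with 778 and 28 at 48 h with 864. Of the 28, 15 were higher with siBRM, among them Pde2a (2.42), the ankyrin-repeat gene Asb2 (2.05) and Hrc (1.81), and 13 were lower, among them Fjx1 (-2.79), Slc1a3 (-2.45) and Lgals3bp (-2.11). These genes were chosen for naming after their values were seen. With the fixed BeadChip term, 21 sarcomere genes were higher and 7 interferon genes lower with siBRM when adjusted over the list alone, with 0 over all probes. The same term with other normalizations called 2 genes at 18 h with median scaling, and 76 to 93 at 48 h.

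The 2 siRNAs shared 0 called genes at either time, since limma called 0 for each. At an unadjusted p under 0.05 with the BeadChip as a block, 51 genes had the same direction with both siRNAs at 18 h, out of 280 with siBRM and 657 with siBRG1. At 48 h it was 71, out of 243 and 1150. Independent lists of these sizes would share 8.46 and 12.9, but both siRNAs are set against the same siSCR arrays. Simulated effects that share only those controls gave 101 and 100. The simulated lists were not matched to the observed sizes, so these counts cannot be set against 51 and 71. The covariance of the 2 effects was 0.066 at 18 h and 0.0704 at 48 h, and simulated shared controls alone gave 0.0657 and 0.0654. Where the siSCR arrays differ (siBRM in 1 replicate against siBRG1 in the other), the covariance was 0.0051 and 0.0072 at 18 h (r = 0.02 and 0.03) and -0.088 and -0.080 at 48 h (r = -0.22 and -0.20). The covariance was thus close to that of the shared controls alone, and with separate controls no positive covariance of that size was seen at either time. At 48 h the opposed siBRM replicates enter the values with separate controls. Those values therefore cannot exclude genes that depend on both.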

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

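The differences between the times were tested as planned, and the tests of possible causes in this part were all chosen after the results were seen. For each siRNA the effect against siSCR at 48 h was set against the effect at 18 h, and the values below are 48 h minus 18 h. Limma called 0 genes for either difference (22 for siBRM and 61 for siBRG1 at an unadjusted p under 0.05, where 542 are expected by chance), and the fixed BeadChip term (254 and 477), the fixed replicate term (195 and 404) and the random BeadChip term (259 and 506) also called 0. Apart from cholesterol biosynthesis and TGF-beta targets, the lists below passed camera with the preset correlation, and none passed with an estimated correlation. Of the list calls ended when 1 array was left out without a block, 3 of 11 for siBRM and 10 of 23 for siBRG1 held with the BeadChip as a block.

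For siBRM, the effect on G1/S and DNA replication genes differed between the times by a median of 0.33 (adjusted p = 0.028; adjusted p = 0.704 with an estimated correlation). That on G2/M and mitosis genes differed by 0.28 (0.028; adjusted p = 0.704 with an estimated correlation). Under median scaling these medians were -0.12 and -0.16, where that of all genes was -0.34, so both lists still lay above all genes. Without replicate 2 of siSCR at 48 h they were -0.17 and -0.13. Without replicate 1 of siSCR at 48 h they were 0.83 and 0.61, and without replicate 1 of siSCR at 18 h the G2/M median was 0.44. Both calls ended without replicate 1 (0.263 and 0.518) or replicate 2 (0.275 and 0.144) of siBRM at 18 h, replicate 2 of siSCR at 18 h (0.551 and 0.556) or replicate 2 of siBRM at 48 h (0.537 for each), and that of G1/S without replicate 1 of siBRM at 48 h (0.112). The number of lists called was 2, and 5 and 4 without replicates 1 and 2 of siSCR at 48 h. Cholesterol biosynthesis genes differed by a median of -0.14, since the list moved in opposite directions at the times in both replicates, but the difference did not pass (adjusted p = 0.432).

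For siBRG1, sarcomere genes differed between the times by -0.34, calcium and energy genes by -0.70 and fusion genes by -0.26, with the tests and array omissions given above. G2/M and mitosis genes differed by 0.33 (0.00827; adjusted p = 0.679 with an estimated correlation). The G2/M call ended without replicate 1 of siBRG1 at 18 h (0.352), replicate 2 of siSCR at 18 h (0.422) or replicate 2 of siBRG1 at 48 h (0.146), and without replicate 2 of siSCR at 48 h the median was -0.04. It was 0.75 without replicate 1 of siSCR and 0.21 without replicate 1 of siBRG1 at 48 h. Extracellular matrix genes differed by 0.24 (0.00317; adjusted p = 0.285 with an estimated correlation). The matrix call ended without replicate 1 of siBRG1 at 18 h (0.0664), replicate 2 of siSCR at 18 h (0.0528) or replicate 2 of siSCR at 48 h (0.217). Its median was 0.41 and 0.52 without replicate 1 of siSCR and replicate 2 of siBRG1 at 18 h, and 0.50, 0.47 and 0.37 without replicate 1 of siSCR, replicate 1 of siBRG1 and replicate 2 of siBRG1 at 48 h.

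Interferon response genes differed between the times with siBRG1 by 0.36 (0.00827; adjusted p = 0.271 with an estimated correlation, and 0.0554 with the BeadChip as a block). The interferon call ended without replicate 1 of siBRG1 at 18 h (0.279), replicate 2 of siSCR at 18 h (0.27), replicate 1 of siSCR at 48 h (0.0898) or replicate 2 of siBRG1 at 48 h (0.281). Its median was 0.54 without replicate 1 of siSCR and 0.64 without replicate 2 of siBRG1 at 18 h. Immediate early genes differed by 0.61 (0.00428; adjusted p = 0.271 with an estimated correlation). That call ended without replicate 1 of siSCR (0.149), replicate 1 of siBRG1 (0.0664) or replicate 2 of siBRG1 (0.0506) at 18 h, or replicate 2 of siSCR at 48 h (0.0576). The number of lists called was 7, and 3, 2, 4 and 2 without replicate 1 of siBRG1, replicate 2 of siSCR and replicate 2 of siBRG1 at 18 h and replicate 2 of siSCR at 48 h. TGF-beta and SRF/YAP targets differed by 0.28, since the list moved in opposite directions at the times in both replicates, but the difference did not pass (adjusted p = 0.369).

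The opposed siBRM replicates at 48 h (r = -0.35 across genes) were weighed first. Normalization as the cause is argued against, since the correlation was -0.33 at its highest and -0.47 at its lowest over 4 normalizations. A swap of the siSCR and siBRM arrays in 1 replicate stays open, because the smaller Smarca2 difference was -0.48, which is -1.08 standard errors, against -1.6 in the other replicate. The unnormalized Smarca2 signal of siBRM minus siSCR was -414 (bead standard error 43.7) in replicate 1 and -643 (55.7) in replicate 2. A swap would make it higher with siBRM in 1 of them, but bead errors leave out the spread between arrays. Replicates at different points of differentiation may have contributed, as the difference between the replicates correlated with the time course of the siBRG1 arrays (r = 0.29, and 0.11 and 0.44 with each replicate of those alone). With 2 replicates this cannot be told apart from other differences between them, which include the BeadChip. The opposition was seen for siBRM against siSCR. With the same siSCR arrays, siBRG1 minus siSCR at 48 h correlated between the replicates with r = 0.20. Without them, siBRM minus siBRG1 at 48 h correlated with r = 0.39. These values do not show which arrays the opposition comes from. The G1/S median at 48 h was 10.23 and 9.24 with siSCR in replicates 1 and 2, against 10.1 in each with siBRM. The stress median was 10.29 and 12.15 with siSCR, against 11.38 and 10.84 with siBRM.

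The higher interferon list with siBRG1 at 48 h was weighed next. A response to any targeting siRNA stays open. The list was lower with siBRM than with siBRG1 in both replicates (median -0.71) and differed from siSCR by 0.07 with siBRM. With an estimated correlation the adjusted p was 0.0123 without a block, but 0.0661 with the BeadChip as a block. The median of siBRM minus siBRG1 was -0.41 with genes at background held at their bound. A response to the sequence of the siBRG1 duplex could explain the median of 0.51. It cannot be told apart from an effect of lower BRG1, because the labels give 1 siRNA against Smarca4.

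The lower sarcomere list with siBRG1 at 48 h was weighed last. Array brightness acting on bright genes stays open, because the test matched random lists on mean expression and not on expression at 48 h. The lowest 2.5% of these lists reached -0.1 (-0.15 and -0.12 in the replicates), against -1.07 for the sarcomere list. The sarcomere medians with siSCR were 8.61 and 8.75 at 18 h but 11.49 and 12.97 at 48 h. The matched lists may therefore be dimmer at 48 h. Lists brighter than the sarcomere at 48 h differed less with siBRG1. Their medians were -0.1 for oxidative phosphorylation, -0.03 for ribosomal proteins and 0.17 for housekeeping genes. An effect of position on the BeadChip stays open, as siBRG1 took the last of the 3 positions in every set. The siBRM arrays in the middle position had a median of -0.01, and the position of siBRG1 cannot be told apart from the siRNA. Another siRNA against Smarca4 or another array order, which the samples do not hold, would be needed to test a dependence of these genes on BRG1.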

How the results depend on the processing

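The combinations of another normalization with the BeadChip block, the bounds for genes at background, the omission of each array in the tests of lists, and every omission with the BeadChip block, were chosen after seeing the data. Where an array was left out, the lone array of that group was assumed to vary like the other groups. Without a block such a group rests on 1 BeadChip, so the shift between BeadChips enters its differences. Unless named here, the cause of a change was not tested.

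The 4 siRNA target differences kept their direction under every alternative run. Over the omission of 1 array, Smarca2 with siBRM ranged from -2.20 to -0.14 at 18 h and from -1.08 to -0.10 at 48 h, and Smarca4 with siBRG1 from -2.18 to -0.23 and from -2.71 to -1.17. The BeadChip block narrowed these ranges to -1.67 to -0.67, -0.75 to -0.43, -1.49 to -0.92 and -2.34 to -1.55. With the BeadChip block, Smarca4 at 48 h passed under median scaling (-1.92, adjusted p = 0.0138), without background correction (-0.99, 0.0368) and with the authors' values (-0.99, 0.0371). Over the other alternatives its adjusted p lay between 0.0956 and 1.

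The 35 genes called between the times were 0 under median scaling, 55 with a stricter detection filter, 179 with the BeadChip block, 287 with the replicate block and 300 with the random BeadChip term. They were 0 to 16 with 1 array left out, where fewer samples lower the number of calls, and 0 to 940 with the block as well. With the BeadChip block they were 740 under median scaling, 550 without background correction and 550 with the authors' values. For siBRG1 against siSCR at 48 h the count of 0 became 11 with the random BeadChip term, and with the BeadChip block 274 under median scaling, 80 without background correction and 80 with the authors' values. Between the siRNAs at 48 h it became 28 with the random BeadChip term, and with the BeadChip block 76, 93 and 93 in the same order. At 18 h that block called 2 under median scaling. The blocked fits changed no other count of called genes.

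Camera with an estimated correlation called fewer lists. It called 0 for siBRM against siSCR at 18 h and 0 at 48 h, 1 for siBRG1 at 18 h and 4 at 48 h, 0 between the siRNAs at 18 h and 4 at 48 h, 3 between the times, and 0 for either difference of effects. With the BeadChip block as well it called 0 in every comparison, the rise of the sarcomere list between the times included. That version has 4 residual degrees of freedom and was not tried on simulated data. Its lack of calls is therefore no evidence against a shift. Median scaling called 0 lists for siBRM at 18 h, 1 at 48 h and 0 for the difference of the siBRM effects. The authors' values called 9 between the siRNAs at 18 h.

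With 1 array left out, the lists called ranged from 0 to 2 for siBRM at 18 h, 1 to 7 for siBRG1 at 18 h, 0 to 6 for siBRM at 48 h, 7 to 10 for siBRG1 at 48 h, 1 to 5 between the siRNAs at 18 h, 7 to 8 at 48 h, 8 to 11 between the times, 0 to 5 for the difference of the siBRM effects and 2 to 9 for that of siBRG1. In the same order, the block gave 0 to 1, 2 to 9, 2 to 6, 6 to 11, 2 to 6, 7 to 10, 8 to 12, 0 to 5 and 1 to 9. Of 252 values for called lists, 91 lost the call or the direction without the block and 81 with it, 66 of them in both.

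Under median scaling the median of all genes was -0.26 for siBRM at 48 h, -0.18 for siBRG1 at 48 h, 0.11 between the siRNAs at 18 h and 0.27 between the times. In the same order it was 0.03, 0.04, -0.01 and -0.06 with the main normalization, and the list medians named next come from median scaling. Below 0 there, but above the median of all genes, were the siBRM medians at 48 h of G1/S (-0.12) and G2/M (-0.17) and the stress median with siBRG1 at 48 h (-0.009). The same holds for the differences between the times of G1/S and G2/M with siBRM (-0.12 and -0.16, against -0.34 for all genes). Over the omission of 1 array, medians that changed sign ranged as follows. With siBRM at 48 h, G1/S ranged from -0.18 to 0.77 and G2/M from -0.20 to 0.58. With siBRG1 at 48 h, G1/S ranged from -0.093 to 0.84, G2/M from -0.007 to 0.76, immediate early genes from -0.008 to 0.75 and the stress response from -0.26 to 1.05. The myogenic factors with siBRG1 at 18 h ranged from -0.48 to 0.057, and the stress response between the siRNAs at 48 h from -0.57 to 0.033. For the difference between the times, G1/S with siBRM ranged from -0.17 to 0.83, G2/M with siBRM from -0.13 to 0.61 and G2/M with siBRG1 from -0.038 to 0.75. Sign changes with the block were G1/S (-0.09) and G2/M (-0.202, and -0.046 without replicate 2 of siBRM) with siBRM at 48 h, and G1/S (-0.065), immediate early genes (-0.035) and stress (-0.171) with siBRG1. Between the siRNAs at 48 h they were G2/M (0.047) and stress (0.113), and between the times G1/S (-0.076) and G2/M (-0.065) with siBRM and the sarcomere (0.022) with siBRG1.

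Of the values for the called lists and the genes with the largest called rises and falls between the times, 632 kept their direction and side of the threshold and 291 kept their direction and were no longer past it. The 27 that changed sign are list medians. Other genes are outside these counts. For siBRM, named genes that kept their direction numbered 48 of 66 at 48 h without replicate 2 of siSCR (45 with the block), 49 of 66 at 18 h without replicate 1 of siBRM, 52 of 66 at 18 h without replicate 2 of siSCR and 52 of 66 at 48 h under median scaling. With genes at background held at their bound, the sarcomere median with siBRG1 was -0.44 at 18 h and -1.06 at 48 h. Signal over background limits genes near the detection limit, whose differences shrink without background correction, as for Smarca4 at 48 h (-0.99 against -1.94).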
